A study of Mus musculus with 8 samples.

How the data were processed

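Polyadenylated RNA from mouse cerebellum was sequenced as paired-end reads of 2 x 100 bases, in 8 libraries, per the labels. Each library was a pool of 3 cerebella from mice labelled male, of the C57Bl/6 strain and at postnatal day 40. Groups were taken from the genotype and activity labels, which gave 4 groups of 2 libraries, and the libraries of a group differ in a lane letter (A or B). The submitters' processing notes name TopHat2 2.0.8b, TopHat, Cufflinks 2.1.1, Cuffdiff and the genome build mm10, without saying what each was used for. The depth of each library is not given in the sources used here, so no counting interval could be computed.

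The 4 tables used here compare a pair of groups each. Per the file headers they are Cuffdiff output, with 1 FPKM value (a fragment count scaled for transcript length and library size) for each group, in which the authors combined the libraries of a group. The FPKM of a group was checked across the deposited tables, and all 13151 values that could be compared were identical, so each is printed as the authors' value without an SD. The log2 values are the deposited fold changes of the second group over the first, per the file headers, and were turned here to cKO over control or runner over sedentary. The deposited test statistic, used here as a score, is Cuffdiff's own for the log2 fold change, per the file headers. The p-value and q-value of each gene are the authors', per the file headers; the smallest p was 5e-05, and each of the 626 distinct p values had 1 q, shared by the 4 tables. The highest q in each table was 0.0631, 0.0530, 0.0264 and 0.0343 (sedentary genotype, runner genotype, cKO running, control running), so the tables hold lists of called genes. No libraries were tested here, since only group values were used.

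Genes were called at q below 0.05, and those higher and lower were counted separately. Genes near 0 in a group may be missing from a table, so a missing gene was never read as unchanged. The number of genes tested was inferred from the count of listed genes and the highest p of each table, taking 0.05 as the cutoff (median 15167). It was used for the overlap of independent lists and in the simulations. The highest q differed between tables, so this number is approximate. Overlaps were described by the genes called in both comparisons and the share with the same direction, with exact binomial tests (two-sided) and Clopper-Pearson intervals, which treat genes as independent. For comparisons that share a group, 100 sets of unchanged groups were simulated with the sharing kept, taking as many top genes as were called. A version with a genotype effect shared by both cKO groups and no running effect was added after the data were seen, its size set by the share of genotype calls with the same direction. The difference between the running responses was tested per gene with a two-sided z test, with the standard error taken as the fold change divided by the deposited statistic, and Benjamini-Hochberg adjustment. Among genes above the smallest p, the median ratio of the statistic to the normal quantile of its p was 0.72. Their standard errors are therefore wide relative to the deposited p. For genes at the smallest p this was not checked. Only genes listed for both members of a pair of comparisons could be tested. The test above 1.5-fold (0.585 log2) was chosen after the data were seen.

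Gene lists, 33 in number and with 9 to 58 members, were written before the data were examined, as were the comparisons, the rule for named genes and most of the other settings tried. They cover the cell types of the cerebellum and of adjoining tissue, and secretory, growth factor, stress, hormone, clock, channel, matrix, ribosomal and respiratory genes. Some genes are on more than 1 list. Because the tables hold called genes, each list was tested by Fisher's exact test (two-sided) of higher against lower among its called members against other called genes, adjusted over the 33 lists of a comparison. Not called members include those that another table lists and the table in question does not. Each list's median was also placed among 10000 random lists of called genes matched on expression. Counts adjusted over the list alone use Benjamini-Hochberg on the deposited p of its listed members. Transcript length was taken from the GENCODE M21 annotation. A length-centred alternative, added after the data were seen, subtracts from each fold change the median of called genes of like length in 20 bins.

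Genes were named by rule: Smarca5 and Vgf in every comparison; the 10 largest increases and 10 largest decreases among called genes with an FPKM of at least 1 in at least 1 group, without predicted genes, small RNAs and loci that join several symbols; up to 4 members per list with the smallest q, ties broken by size of change; and for reversal the 10 genes whose smaller change was largest, where the same filters were applied although the rule as written gave them for the largest changes alone. Some genes that the rule names are counted but not reported here by name. The sex-linked genes were added after the data were seen. The other settings tried were a q threshold of 0.01, changes of at least 1 or 0.585 log2, an FPKM of at least 1, pseudocounts of 1 and 0.1, and loci with a single symbol. On simulated data of 11763 genes, the test of the difference found 36%, 77% and 99% of 100 genes that differed by 0.585, 1 and 2 log2, and 6.61% of its 227 calls were unchanged genes. The list test passed 100% of 20 raised lists and 1% of 100 unchanged lists. The simulated noise came from the standard errors that the test uses, genes were independent, and the test of the difference was given every gene. These rates therefore do not cover co-expressed lists or the selection of called genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.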

Results

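RNA-seq of mouse cerebellum at postnatal day 40 compared control mice with Snf2h cKO-Nestin mice, each kept sedentary or allowed to run. Snf2h, encoded by Smarca5, is the ATPase of the ISWI chromatin remodelling complexes, and the conditional knockout (cKO) removes it from the neural cells in which the Nestin driver acts. The 4 groups (control sedentary, control runner, cKO sedentary and cKO runner) held 2 libraries each, and the labels describe each library as a pool of 3 cerebella. The libraries of a group differ in title only by a lane letter. The series design speaks of biological replicates, but whether the letters mark separate pools or sequencing lanes of 1 pool is not stated. The sequencing depth of each library is unknown. The deposited tables give 1 FPKM value per group, so no spread between replicates can be shown, and the error behind each call is the authors' own.

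The 4 deposited tables listed 9971 genes for cKO over control in sedentary mice, 8105 for cKO over control in runners, 3712 for runners over sedentary mice in the cKO and 4771 for runners over sedentary mice in the control. A gene was called at a deposited q below 0.05, and nearly every listed gene met this. The highest q listed was 0.0264 for running in the cKO and 0.0343 for running in the control. A gene that a table does not list was thus not tested or not called. For the running comparisons it may also have a q between these values and 0.05. Counts of called and not called genes for running therefore stand at a stricter cut than those for genotype. In all, 11763 genes were listed in at least 1 table and 7303 had a value in all 4 groups. Unless another q is given, each call of a gene named below had q = 0.000167, the smallest in the tables. A value given for a gene that was not called carries no such q.

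The targeted gene was lower in both cKO groups. Smarca5 (XLOC_022608), a protein-coding gene on the minus strand of chromosome 8 from 80698507 to 80739497 (mm10), had 12.6 FPKM in control sedentary, 13.0 in control runner, 4.94 in cKO sedentary and 5.38 in cKO runner, per the authors' deposited table. Its log2 fold change in the authors' deposited table was -1.35 in sedentary mice and -1.27 in runners, so transcript remained in the cKO pools. Neither running table listed Smarca5.

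Vgf, which encodes a secreted neuropeptide precursor and is the gene named in the series title, was higher in the cKO and higher again in cKO runners. Vgf (XLOC_017241; plus strand of chromosome 5, 137026392 to 137033351) had 11.97 FPKM in control sedentary, 10.7 in control runner, 24.8 in cKO sedentary and 33.2 in cKO runner, per the authors' deposited table. The authors' deposited table gave log2 fold changes of 1.05 for cKO over control in sedentary mice, 1.63 in runners and 0.42 for running in the cKO. Vgf was not listed for running in the control. Hindbrain and midbrain genes, described below, were also higher in both cKO groups. With running in the cKO, 10 of them were higher and 1 lower, which did not pass. The part of such tissue in the Vgf values was not tested. The running response of Vgf was larger in the cKO than in the control by 0.58 log2 (SE 0.19), at an adjusted p of 0.00868 for any difference; the test for a difference above 1.5-fold was not passed.

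**Figure D1:**
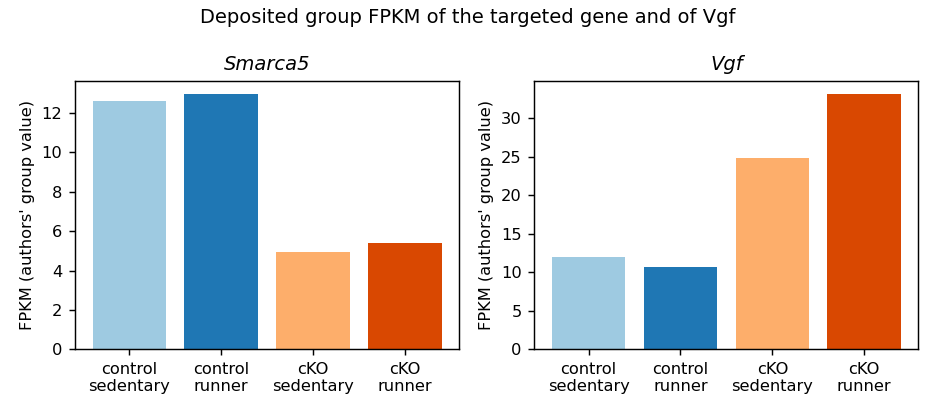
Group FPKM of Smarca5 (left) and Vgf (right) in the 4 groups, as the authors' deposited tables give them; each bar is the single group value, drawn from 0 with no error bar. Smarca5 lies near 13.0 in both control groups and near 5 in both cKO groups, while Vgf rises from 11.97 and 10.7 in control to 24.8 and 33.2 in cKO.

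Cell identity transcripts differed widely between cKO and control cerebella of sedentary mice. Granule neuron genes were lower in the cKO, and genes of Purkinje cells, glia, microglia, meninges, extracellular matrix and the interferon response were higher. FPKM values are relative, so a lower share of granule neurons would by itself raise markers of other cell types. Its part in the Purkinje cell, glial and microglia results, here or in runners, was not tested. This comparison asks how cKO and control cerebella differ in sedentary mice. It called 9725 genes, of which 4520 were higher and 5205 lower in the cKO. Large changes were mostly increases: 1332 genes rose and 575 fell by at least 2-fold, genes listed at 0 in 1 group included, while 53.4% of called genes changed by less than 1.5-fold.

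Of the 27 granule neuron genes listed in any table, 1 rose, 25 fell and 1 was not called (adjusted exact p = 1.24e-05, Fisher's exact test of the split in direction against other called genes, as for the other lists). The authors' deposited table put Neurod1, a granule neuron transcription factor, at 37.8 FPKM in cKO and 270.1 in control (log2 -2.84). The authors' deposited table gave -2.51 for Gabra6, the granule-specific GABA-A receptor subunit, -2.47 for Calb2 and -2.18 for Gabrd. Purkinje cell genes went the other way, with 27 higher, 1 lower and 1 not called (adjusted exact p = 1.27e-07). The authors' deposited table gave 1.42 for Slc1a6, the Purkinje cell glutamate transporter, 1.42 for Itpr1 and 1.14 for Dagla. Inhibitory interneuron genes did not pass (10 higher, 5 lower, adjusted exact p = 0.184), although Gad2 rose by 1.35 in the authors' deposited table.

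Oligodendrocyte lineage genes were higher in the sedentary cKO. Among mature oligodendrocyte and myelin genes 21 rose, 7 fell and 5 were not called (adjusted exact p = 0.00847), and among precursor genes 14 rose, 1 fell and 2 were not called (adjusted exact p = 0.000806). The authors' deposited table gave 1.78 for Adamts4, 1.36 for Myrf, the myelin gene regulator, 1.33 for Olig2, a lineage transcription factor held by both lists, and 1.17 for Gpr17. Astrocyte and Bergmann glia genes numbered 18 higher, 7 lower and 2 not called (adjusted exact p = 0.0265), with Gfap at 348 against 110 FPKM in the authors' deposited table. Microglia genes numbered 17 higher, 1 lower and 3 not called (adjusted exact p = 0.000115). Interferon and antigen presentation genes numbered 24 higher, 2 lower and 1 not called (adjusted exact p = 5.98e-06), and the authors' deposited table gave 2.43 for Usp18, 2.36 for Oasl2 and 2.14 for Irf7, all interferon-induced.

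Extracellular matrix genes rose in 31 cases and fell in 1, with 6 not called (adjusted exact p = 8.89e-09). Growth and neurotrophic factor genes numbered 20 higher, 5 lower and 2 not called (adjusted exact p = 0.00252). The authors' deposited table gave 2.47 for Dlk1, 2.16 for Il33 and 1.72 for Igf2, but -2.93 for Ntf3, the neurotrophin-3 gene. The list of 58 clustered protocadherins, the cell surface adhesion proteins, came down to 15 listed loci. Of these, 1 rose, 12 fell and 2 were not called (adjusted exact p = 0.00961), with -1.65 for Pcdhb15 in the authors' deposited table. The locus joining the Pcdha and Pcdhg symbols was not lower, at 247 FPKM in cKO sedentary and 194 in control sedentary. Cytosolic ribosomal protein genes fell in 39 cases with 2 not called, and oxidative phosphorylation genes fell in 36 with 1 not called (adjusted exact p = 9.46e-10 and 3.32e-09). The direction of change followed transcript length in this comparison: 23.1% of called genes with a longest transcript under 1 kb were higher in the cKO, against 65.1% of those over 6 kb. With fold changes centred on genes of like length, oxidative phosphorylation genes split 17 higher and 19 lower (adjusted exact p = 0.868) and ribosomal protein genes 4 higher and 35 lower (adjusted exact p = 2.63e-06).

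The largest increases in the authors' deposited table were Clrn2 (7.82, q = 0.0351), the dopamine transporter Slc6a3 (5.67, q = 0.0144), Glra4 (5.40), Iyd (4.89), Nphs1 (4.49), Prokr2 (4.46), the noradrenaline transporter Slc6a2 (4.29), Slc17a8 (4.01), Gipr (3.94) and Kirrel2 (3.56). The largest decreases in the authors' deposited table were the protease gene Klk6 (-4.88, from 17.0 to 0.576 FPKM), Prss41 (-4.62, q = 0.00658), Akr1b7 (-3.90, q = 0.00905), Tgm5 (-3.31), Cabp2 (-3.14), Ntf3, Neurod1, Emilin3 (-2.81), Car4 (-2.66) and Stap2 (-2.64). Each of the largest increases had under 1 FPKM in control sedentary (0.0073 for Clrn2, 0.035 for Slc6a3), so its size rests on a low control value. Markers of tissue next to the cerebellar cortex moved with the changes above. Choroid plexus genes rose in 17 cases and fell in 1 (adjusted exact p = 0.000115), at 640 FPKM of Ttr in cKO and 77.7 in control in the authors' deposited table. Hindbrain and midbrain genes rose in 20 cases with 2 not called (adjusted exact p = 1.43e-06), and meninges and fibroblast genes rose in 17 with 2 not called (adjusted exact p = 1.02e-05). Adjusted over the list alone, 1 more gene rose for neuropeptide (12), endothelial (10), meninges (18), proliferation (10), histone (3), stress response (9), heat shock (6) and receptor genes (17), 1 more fell for cholesterol (15), oxidative phosphorylation (37) and ribosomal protein genes (40), and other lists kept their counts.

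**Figure D2:**
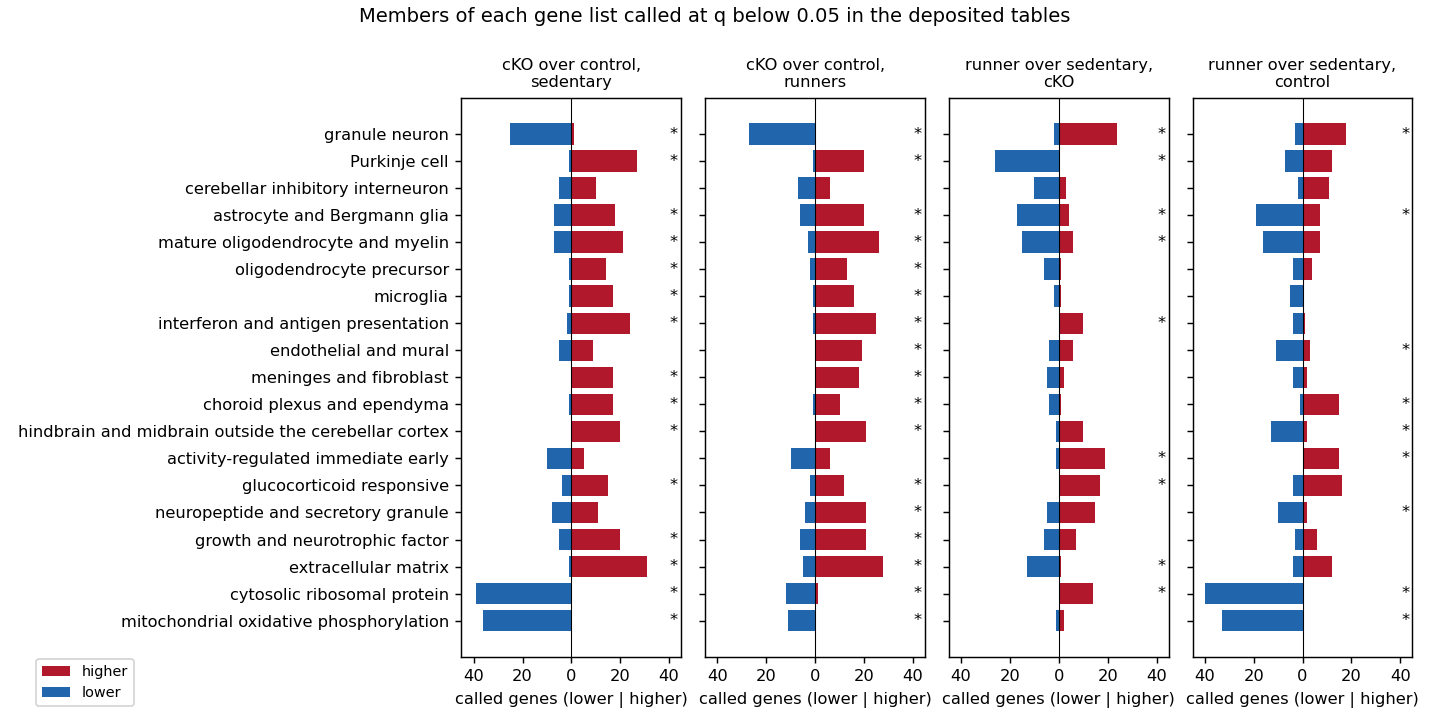
Number of called members of 19 gene lists that were higher (red, right) or lower (blue, left) in each of the 4 comparisons, from the authors' deposited tables; an asterisk marks a list whose split differed from that of other called genes at an adjusted p below 0.05. Granule neuron genes are lower and Purkinje cell genes higher in both cKO over control panels (25 lower and 27 higher in sedentary mice), and both lists switch side in the panel of running in the cKO.

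Runners showed much of the same cKO pattern, with a median change among called genes of 1.37-fold against 1.46-fold in sedentary mice. Granule neuron genes were again lower, and genes of oligodendrocytes, microglia, matrix and the interferon response again higher. This comparison asks how far cKO and control cerebella differ after running. It called 8051 genes, 3790 higher and 4261 lower in the cKO. By at least 2-fold, 897 rose and 325 fell, and 63.5% of called genes changed by less than 1.5-fold.

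All 27 listed granule neuron genes fell (adjusted exact p = 1.14e-06). The authors' deposited table gave -1.74 for Gabra6, -1.74 for Neurod1, -1.65 for Gabrd and -1.52 for Fat2. Purkinje cell genes numbered 20 higher, 1 lower and 8 not called (adjusted exact p = 2.25e-05), with 0.82 for Slc1a6 and 0.73 for Pcp2 in the authors' deposited table. Mature oligodendrocyte genes numbered 26 higher, 3 lower and 4 not called (adjusted exact p = 1.12e-05), and precursor genes 13 higher, 2 lower and 2 not called (adjusted exact p = 0.0063). The authors' deposited table gave 1.1 for Myrf, 0.95 for Sox10, 1.29 for C1ql1 and 1.25 for Bmp4. Astrocyte and Bergmann glia genes rose in 20 cases and fell in 6, with 1 not called (adjusted exact p = 0.00615), and Gfap reached 280 FPKM against 80.2 in the authors' deposited table. Microglia genes rose in 16 cases and fell in 1, with 4 not called (adjusted exact p = 0.000271). Endothelial and mural genes, which in sedentary mice numbered 9 higher and 5 lower (adjusted exact p = 0.266; 0.0266 length-centred), rose in 19 cases with 3 not called (adjusted exact p = 4.89e-06), with 0.90 for the lipid transporter gene Mfsd2a in the authors' deposited table.

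Interferon and antigen presentation genes rose in 25 cases and fell in 1, with 1 not called (adjusted exact p = 1.69e-06). The authors' deposited table gave 2.71 for Irf7, 2.69 for Usp18, 2.69 for Oasl2 and 2.52 for Oas1a. Neuropeptide and secretory granule genes, the list that holds Vgf, numbered 21 higher, 4 lower and 2 not called (adjusted exact p = 0.000614), but did not pass in sedentary mice (11 higher, 8 lower and 8 not called, adjusted exact p = 0.478). Length-centred, the contrast was smaller, with 14 higher and 5 lower in sedentary mice (adjusted exact p = 0.0995) and 22 and 2 in runners. The authors' deposited table gave 4.19 for Cartpt, 3.39 for Calca and 2.20 for Pdyn, and listed Ucn at 0 in control runner and 1.64 FPKM in cKO runner. Growth factor genes numbered 21 higher and 6 lower (adjusted exact p = 0.00432), and the authors' deposited table gave 3.21 for Dlk1 and 2.1 for Il33. Extracellular matrix genes numbered 28 higher, 5 lower and 5 not called (adjusted exact p = 4.46e-05). Clustered protocadherin loci numbered 1 higher, 13 lower and 1 not called (adjusted exact p = 0.00569). The locus joining the Pcdha and Pcdhg symbols was not lower, at 225 FPKM in cKO runner and 210 in control runner. Ribosomal protein genes numbered 1 higher, 12 lower and 28 not called (adjusted exact p = 0.00825; 1 once length-centred), and oxidative phosphorylation genes 11 lower and 26 not called (adjusted exact p = 0.00347).

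The largest increases in the authors' deposited table were the Y-linked Eif2s3y (7.38), Slc6a3 (7.31, q = 0.000906), Glra4 (5.26), the serotonin transporter Slc6a4 (5.0), Dbh (4.98), Slc6a2 (4.90), Slc18a3 (4.86, q = 0.00916), Slc10a4 (4.66), Iyd (4.35) and the serotonin synthesis gene Tph2 (4.35). The largest decreases in the authors' deposited table were Klk6 (-4.66), Akr1b7 (-2.45, q = 0.000765), Scnn1g (-2.38), Emilin3 (-2.37), Cd70 (-2.31, q = 0.000765), Tssk5 (-2.27, q = 0.00172), Cabp2 (-2.22, q = 0.000765), Vipr1 (-2.14), Slco2a1 (-2.13) and Sebox (-2.12). All of the largest increases but Tph2 had under 1 FPKM in control runner (0.051 for Slc6a3), so their size rests on low control values. Monoamine neuron genes among the increases belong to the hindbrain and midbrain list, in which 21 genes rose and 1 was not called (adjusted exact p = 1.69e-06). Choroid plexus genes rose in 10 cases and fell in 1, with 7 not called (adjusted exact p = 0.00825), and meninges genes rose in 18 with 1 not called (adjusted exact p = 8.33e-06). Transcript length hardly separated the directions here, with 44.4% of called genes under 1 kb and 43.7% over 6 kb higher in the cKO. Adjusted over the list alone, 17 microglia and 13 glucocorticoid responsive genes rose, 9 oxidative phosphorylation genes fell, 11 ribosomal protein genes fell with none higher, and other lists kept their counts.

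The 2 genotype comparisons share no library, and 6642 genes were called in both. Of these, 6275 (94.5%, exact Clopper-Pearson 95% interval 93.90 to 95.01%) changed in the same direction, 2964 higher and 3311 lower in the cKO, and 367 in opposite directions. Independent lists of these sizes would share 2592 genes in the same direction. Length-centred, 91.8% of genes had the same direction. Smarca5, Klk6, Neurod1, Gabra6, Gfap, Irf7, Dlk1 and Vgf kept their direction.

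In the cKO, granule neuron and activity-regulated genes were higher, and Purkinje cell, astrocyte and matrix genes lower, in runners than in sedentary mice. Most changes were small, with 85.4% of called genes under 1.5-fold. This comparison asks how runners differ from sedentary mice in the cKO cerebellum. It called 3712 genes, 2086 higher and 1626 lower in runners, and 75 rose and 66 fell by at least 2-fold. Longer transcripts were less often higher: 61.2% of called genes with a longest transcript under 1 kb were higher in runners, against 39.5% of those over 6 kb.

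Granule neuron genes numbered 24 higher, 2 lower and 1 not called (adjusted exact p = 0.000944). The authors' deposited table gave 1.19 for Barhl1, 0.91 for Neurod1, 0.89 for Uncx and 0.83 for Calb2. Purkinje cell genes fell in 26 cases with 3 not called (adjusted exact p = 1.41e-08), and the authors' deposited table gave -0.71 for Gpr63, -0.71 for Nrk and -0.62 for Ppp1r17. Ataxia-linked channels and receptors, several of which belong to Purkinje cells, numbered 4 higher, 19 lower and 9 not called (adjusted exact p = 0.00102; 0.458 length-centred). Astrocyte and Bergmann glia genes numbered 4 higher, 17 lower and 6 not called (adjusted exact p = 0.00268).

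Oligodendrocyte genes were slightly lower in cKO runners than in sedentary cKO mice. The mature list numbered 6 higher, 15 lower and 12 not called (adjusted exact p = 0.0458). Length-centred, it numbered 1 higher and 20 lower (adjusted exact p = 0.00022). The authors' deposited table gave -0.52 for Adamts4, -0.34 for Tspan2 and 0.35 for Trf, the transferrin gene. The precursor list numbered 1 higher, 6 lower and 10 not called (adjusted exact p = 0.114), with 0.66 for Cnksr3 and -0.51 for Enpp6 in the authors' deposited table. Extracellular matrix genes numbered 1 higher, 13 lower and 24 not called (adjusted exact p = 0.00102).

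Activity-regulated immediate early genes numbered 19 higher, 1 lower and 4 not called (adjusted exact p = 0.00102). The authors' deposited table gave 1.71 for Egr3, 1.59 for Nr4a3, 1.58 for Fosb and 1.13 for Nr4a2. Glucocorticoid responsive genes rose in 17 cases with 3 not called (adjusted exact p = 0.000944), with 1.39 for Sgk1 and 1.32 for Plin4 in the authors' deposited table. Interferon and antigen presentation genes rose in 10 cases with 17 not called (adjusted exact p = 0.0123), with 0.96 for Xaf1 in the authors' deposited table. Ribosomal protein genes rose in 14 cases with 27 not called (adjusted exact p = 0.00228; 0.966 length-centred). Neuropeptide genes numbered 15 higher, 5 lower and 7 not called (adjusted exact p = 0.201), and growth factor genes 7 higher, 6 lower and 14 not called (adjusted exact p = 1). Among the members that rose, the authors' deposited table gave 0.93 for Sst, 0.53 for Chgb, 0.80 for Bdnf, 0.70 for Fgf1 and 0.69 for Nrn1. Igf2, a growth factor gene, went the other way, from 72.6 FPKM in cKO sedentary to 59.1 in cKO runner. Adjusted over the list alone, the 1 histone gene called here was lost and other lists kept their counts.

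The largest increases in the authors' deposited table were Cartpt (2.76), Tagap (2.22), Slc6a3 (2.18), Adamtsl5 (1.75), Egr3, Nr4a3, Tcf7l2 (1.58), Ccdc28b (1.58), Tfap2d (1.40) and Nrgn (1.40). The largest decreases in the authors' deposited table were the neutrophil genes S100a8 (-2.29, q = 0.0107), Ngp (-2.27, q = 0.00817) and S100a9 (-2.25, q = 0.00105), the red blood cell genes Beta-s (-1.69) and Alas2 (-1.68), and Paqr6 (-1.38, q = 0.0127), Xlr3b (-1.37, q = 0.0116), Exd1 (-1.30), Rhbdl2 (-1.16, q = 0.0114) and the Y-linked Ddx3y (-1.15). The red blood cell list numbered 1 higher and 3 lower (adjusted exact p = 0.447), and hindbrain and midbrain genes numbered 10 higher, 1 lower and 11 not called (adjusted exact p = 0.0729; 0.0425 length-centred). Choroid plexus genes numbered 1 higher, 4 lower and 13 not called (adjusted exact p = 0.289).

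In the control, activity-regulated and choroid plexus genes were higher, and ribosomal and hindbrain genes lower, in runners than in sedentary mice. Changes were again small, with 88.6% of called genes under 1.5-fold. This comparison asks how runners differ from sedentary mice in a cerebellum with Snf2h. It called 4771 genes, 2603 higher and 2168 lower in runners, and 85 rose and 54 fell by at least 2-fold. The direction followed transcript length: 8.81% of called genes with a longest transcript under 1 kb were higher in runners, against 87.9% of those over 6 kb (Spearman rho 0.55 across genes, which are not independent replicates).

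Immediate early genes rose in 15 cases with 9 not called (adjusted exact p = 0.000973; 0.00197 length-centred). The authors' deposited table gave 1.70 for Npas4, 1.49 for Nr4a3, 1.28 for Fosl2 and 1.24 for Nr4a1. Glucocorticoid responsive genes numbered 16 higher and 4 lower (adjusted exact p = 0.0567; 0.0042 length-centred), and the authors' deposited table gave 3.41 for Zbtb16, 1.78 for Hif3a, 1.60 for Map3k6 and 1.51 for Fkbp5. Choroid plexus genes numbered 15 higher, 1 lower and 2 not called (adjusted exact p = 0.00823), with Ttr at 518 FPKM in runners and 77.7 in sedentary mice in the authors' deposited table. Hindbrain and midbrain genes numbered 2 higher, 13 lower and 7 not called (adjusted exact p = 0.00823), with -2.89 for Slc6a4 and -2.23 for Tph2 in the authors' deposited table. Neuropeptide genes numbered 2 higher, 10 lower and 15 not called (adjusted exact p = 0.0483; 0.4 length-centred), with -0.96 for Vip and -0.73 for Sst in the authors' deposited table.

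Ribosomal protein genes fell in 40 cases with 1 not called (adjusted exact p = 5.38e-13), and oxidative phosphorylation genes fell in 33 with 4 not called (adjusted exact p = 7.16e-11). Both lists hold short transcripts: length-centred, they numbered 8 higher and 32 lower (adjusted exact p = 0.00283) and 13 higher and 20 lower (adjusted exact p = 0.486). Granule neuron genes numbered 18 higher, 3 lower and 6 not called (adjusted exact p = 0.0173; 0.305 length-centred), and ataxia-linked channels and receptors 26 higher, 3 lower and 3 not called (adjusted exact p = 0.000973; 1 length-centred). Astrocyte and Bergmann glia genes numbered 7 higher, 19 lower and 1 not called (adjusted exact p = 0.0191; 0.414 length-centred), endothelial genes 3 higher, 11 lower and 8 not called (adjusted exact p = 0.0483; 0.598 length-centred), and cholesterol synthesis genes 2 higher, 11 lower and 8 not called (adjusted exact p = 0.0191; 0.123 length-centred). Mature oligodendrocyte genes numbered 7 higher, 16 lower and 10 not called (adjusted exact p = 0.0549), Purkinje cell genes 12 higher, 7 lower and 10 not called (adjusted exact p = 0.547), and precursor genes 4 higher, 4 lower and 9 not called (adjusted exact p = 1). Adjusted over the list alone, the proliferation list lost 1 of its 3 lower genes and other lists kept their counts.

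The largest increases in the authors' deposited table were Zbtb16, Tmem72 (2.97), Ttr (2.74), Folr1 (2.70), Kcne2 (2.61), Cldn1 (2.5), Prlr (2.49), Krt18 (2.45, q = 0.00263), Sostdc1 (2.35) and Wdr86 (2.27, q = 0.000324). Of these, Ttr, Folr1, Kcne2, Prlr and Sostdc1 are on the choroid plexus list. The largest decreases in the authors' deposited table were Eif2s3y (-7.80, q = 0.000475), Slc6a4, S100a9 (-2.44, q = 0.0067), Tph2, Bspry (-1.78), Calca (-1.37, q = 0.0127), Capn11 (-1.21), a locus carrying the symbol Slc6a5 (-1.16, q = 0.00519), Snhg4 (-1.13, q = 0.029) and Fam92b (-1.13, q = 0.0137).

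**Figure D3:**
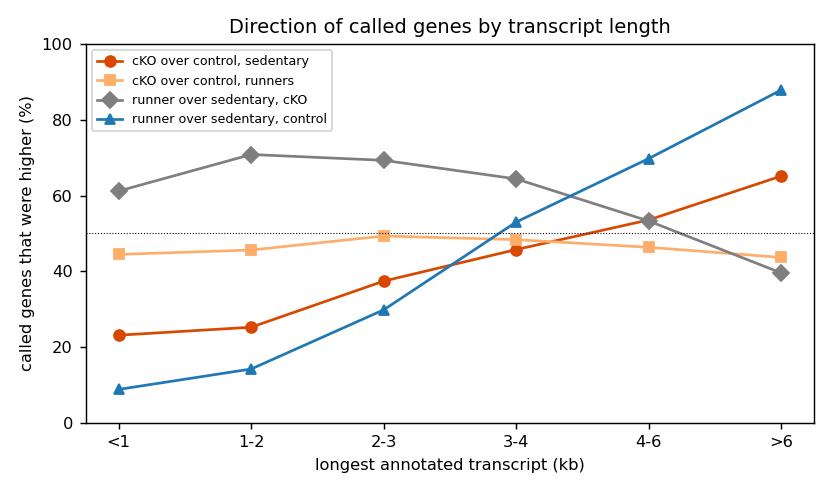
Share of called genes that were higher (vertical axis, percent) by length of the longest annotated transcript (horizontal axis, kb) in each of the 4 comparisons; each point is a bin of called genes, from the authors' deposited tables. The line for running in the control climbs from 8.81% under 1 kb to 87.9% over 6 kb, and the line for cKO over control in runners stays between 43.7% and 49.3%.

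Genes that differed in the cKO mostly moved the other way with running. Of the 3160 genes called both for cKO over control in sedentary mice and for running in the cKO, 2648 (83.8%, exact Clopper-Pearson 95% interval 82.5 to 85.1%) changed in opposite directions and 512 in the same direction. Length-centred, 78.4% of genes had opposite directions in these comparisons. The genes with the largest changes in both, given as the log2 change with genotype and then with running in the authors' deposited tables, included Tagap (-2.35 and 2.22), Tfap2d (-1.58 and 1.40), Tcf7l2 (-1.39 and 1.58), Barhl1 (-1.61 and 1.19) and Adamtsl5 (-1.18 and 1.75). Car9 (-2.45, then 1.17 at q = 0.00387), Alas2 (1.84 and -1.68), Beta-s (1.31 and -1.69), Paqr6 (1.85 at q = 0.00795, then -1.38) and Rhbdl2 (1.46 at q = 0.00542, then -1.16) completed the 10 in the authors' deposited tables. The joined haemoglobin locus Hbb-b1,Hbb-b2 (2.27 and -1.85 in the authors' deposited tables) was left out by the filters for named genes. Alas2, Beta-s and this locus are red blood cell genes, and the amount of blood in the pools is not known. Both comparisons use the cKO sedentary libraries, and simulated unchanged groups that share a group in this way gave 90.1% in opposite directions. Simulated groups with no running effect and a genotype effect shared by both cKO groups, of a size that gave the 94.5% above, had 73.8% in opposite directions, so most of this count can arise without a reversal. Set instead against cKO over control in runners, 1919 of 2815 genes (68.2%, interval 66.4 to 69.9%, or 65.2% length-centred) were still opposite. That comparison shares the cKO runner libraries and so favours the same direction. There the simulated groups with a genotype effect gave 24.0% opposite and unchanged groups 7.97%. All simulated groups had equal spread, so these shares do not cover cKO sedentary pools that stand apart for another reason. Whether running or such pools set the direction was not tested.

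The running responses of the genotypes shared their direction no more often than not. Of the 2082 genes that running changed in both genotypes, 1043 (50.1%, exact Clopper-Pearson 95% interval 47.9 to 52.3%) moved in the same direction and 1039 in opposite directions (two-sided exact binomial p = 0.948). Among the genes changed by at least 1.5-fold in both, 55 moved in the same direction and 21 in opposite directions (72.4% in the same direction, exact binomial p = 0.000121). Immediate early genes rose in both genotypes, 19 against 1 in the cKO and 15 with none lower in the control.

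**Figure D4:**
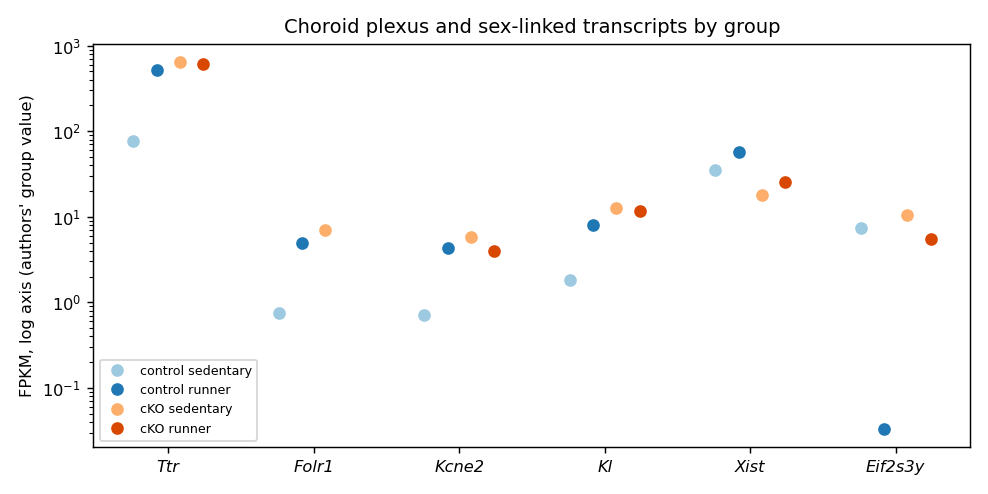
Group FPKM (vertical log axis) of 4 choroid plexus genes (Ttr, Folr1, Kcne2 and Kl) and of the sex-linked Xist and Eif2s3y in the 4 groups, as the authors' deposited tables give them; each point is 1 group, and Folr1 has no point for cKO runner because no table lists it there. Control sedentary lies lowest for the choroid plexus genes (77.7 FPKM for Ttr against 518 or more elsewhere), and control runner lowest for Eif2s3y at 0.0334.

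Per gene, 7294 genes could be tested for a difference between the running responses, and 2256 differed at an adjusted p below 0.05, with 1059 more positive and 1197 more negative in the cKO. A difference above 1.5-fold was shown for 75 genes, 19 more positive and 56 more negative in the cKO. For lists, Fisher's exact test took genes as independent, although the counts of the 2 genotypes hold many of the same genes. Its p therefore measures no spread between libraries. By Fisher's exact test on direction, lists whose called members differed between the genotypes included ribosomal protein genes (adjusted exact p = 1.02e-11), ataxia-linked channels (2.11e-06), Purkinje cell genes (1.93e-05), hindbrain and midbrain genes (0.00139), extracellular matrix genes (0.00152), neuropeptide genes (0.0152), and interneuron, choroid plexus, interferon and oxidative phosphorylation genes (0.0159 each). Length-centred, 5 of these 10 lists still differed, namely Purkinje cell, choroid plexus, hindbrain and midbrain genes (adjusted exact p = 0.00324 each), extracellular matrix genes (0.00657) and interferon genes (0.0242). Ribosomal protein and interneuron genes (adjusted exact p = 0.0798 each), neuropeptide genes (0.25), ataxia-linked channels (0.748) and oxidative phosphorylation genes no longer did. The neuropeptide list, which had not passed in the cKO, numbered 12 higher and 8 lower there length-centred, against 3 and 9 in the control. Mature oligodendrocyte genes did not pass this test (6 higher and 15 lower in the cKO, 7 higher and 16 lower in the control, adjusted exact p = 1). Length-centred, they numbered 1 higher and 20 lower in the cKO against 7 and 16 in the control, and still did not pass (adjusted exact p = 0.198).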

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

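All tests of explanations below were chosen after the results were seen, except the comparison of ribosomal protein and oxidative phosphorylation genes with lists matched on transcript length for running in the control; the test of a difference above 1.5-fold was also added after seeing the data. Of 370 named genes, 320 could be tested for a difference between the running response of the cKO and that of the control, and 30 differed by more than 1.5-fold, 11 more positive and 19 more negative in the cKO. The differences given here are log2, the cKO response minus the control response, with no value per library behind them.

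Among genes more positive in the cKO, granule neuron genes were Calb2 (1.22), Neurod1 (1.1) and Gabra6 (0.77). Neuropeptide genes were Cartpt (3.34) and Sst (1.66), and monoamine or glutamate neuron genes of the hindbrain and midbrain list were Slc6a4 (2.76), Tph2 (2.20) and Slc17a6 (0.81). The others were Tcf7l2 (1.82), Nrgn (1.69) and Fgf1 (0.94). Slc6a4 and Tph2 stand here through the control, in which they fell, with values of -0.13 and -0.03 for running in the cKO.

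Among genes more negative in the cKO and reported here, those of the choroid plexus list were Kcne2 (-3.16), Aqp1 (-2.87), Ttr (-2.80), Prlr (-2.45) and Kl (-2.25). Purkinje cell or ataxia-linked genes included Kcnma1 (-0.92), Itpr1 (-0.92), Cacna1g (-0.86) and Cacna2d2 (-0.86). Haemoglobin genes were Hbb-b1,Hbb-b2 (-2.35) and Beta-s (-1.69). Oligodendrocyte lineage genes were Adamts4 (-1.29) and Tnr (-0.91), and the others were Zbtb16 (-2.51), Cldn1 (-2.06) and Igf2 (-0.95).

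Markers of tissue beside the cerebellar cortex differed between the groups: Ttr had 77.7 FPKM in control sedentary, 518 in control runner, 640 in cKO sedentary and 610 in cKO runner, and Tph2 had 4.93, 1.05, 21.8 and 21.3 in the same order. A response to running in both genotypes is argued against for the choroid plexus genes, whose median change with running in the cKO was -0.068 over 13 members, with 10 below 0 and the highest at 0.06. A lower share of granule neurons in the cKO would raise markers of all other cell types alike. It is argued against for choroid plexus genes in sedentary mice, whose lower quartile was 1.48 over 18 called genes. This lay above the upper quartiles of astrocyte (0.72), oligodendrocyte (0.64), Purkinje cell (1.01) and microglia genes (0.95). Hindbrain and midbrain genes had lower quartiles of 1.23 in runners and 0.91 in sedentary mice. These lay above the upper quartiles of astrocyte (0.65 and 0.72) and oligodendrocyte genes (0.49 and 0.64). The 0.91 was below those of Purkinje cell and microglia genes. Only called members enter, and 22 of 36 hindbrain and midbrain genes were listed anywhere, so genes near 0 can enter through a large change. No conclusion is drawn for that list. A lower granule neuron share fits the choroid plexus genes in runners (lower quartile 0.35). More choroid plexus in the pools of the other 3 groups stays open. Of 17 list members, 13 (76.5%) were at least 2-fold higher in control runner than in control sedentary. Tissue amount and a group effect cannot be told apart for these genes, since the design holds no measure of the tissue taken, and an effect of genotype or running on the tissue itself was not tested.

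Sex-linked transcripts were at odds with the male label: Eif2s3y had 7.43 FPKM in control sedentary, 0.0334 in control runner, 10.4 in cKO sedentary and 5.56 in cKO runner, while Xist, made in females, had 34.8, 57.6, 18.1 and 25.8. A failed estimate of the Y-linked gene alone is argued against, because Xist, Eif2s3x, Kdm5c, Kdm6a and Ddx3x had a median log2 change of 0.40 from control sedentary to control runner, at percentile 99.75 of lists of other genes matched on length and expression (central 95% from -0.12 to 0.30). Of these genes, all but Kdm6a were called higher in control runner. Pools of mixed sex, with the control runner pools mostly or wholly female, may account for the pattern. Eif2s3y in control runner was 0.60% of the lowest other group, although no value is listed for Ddx3y, Uty or Kdm5d there. In the cKO, running went with lower Eif2s3y (-0.91), Ddx3y (-1.15), Uty (-0.92) and Kdm5d (-0.88) and higher Xist (0.51). Sex-linked transcripts differ with group here, so sex cannot be told apart from running in either genotype or from genotype in runners. In sedentary mice Xist was lower in the cKO, but the called Y-linked genes split, 1 higher and 2 lower. Sex is therefore not excluded there either. The part of sex in other changes was not tested.

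Ribosomal protein and oxidative phosphorylation genes were highest in control sedentary, with a median log2 change of -0.38 over 73 called members of both lists from control sedentary to control runner. A trend with transcript length as the whole cause is argued against, because lists of other genes matched on expression and length had a median of -0.19 by median coding transcript (central 95% from -0.24 to -0.13) and -0.27 by longest transcript (-0.31 to -0.24), and the observed median was at percentile 0 of 10000 lists either way. Even so, centring on genes of like length, in bins that include these genes, took the oxidative phosphorylation median from -0.36 to -0.03 and ended its call (13 higher, 20 lower), and took the ribosomal median from -0.40 to -0.09 (8 higher, 32 lower, still past the threshold). A response to running in both genotypes is argued against only for the ribosomal protein genes called for running in the cKO, of which 14 rose and none fell. With 3 oxidative phosphorylation genes called there, no conclusion is drawn for that list, and members not called could not enter. The 17 called members of both lists had a median of 0.16, at percentile 90.4 of their matched lists (88.5 by longest transcript). Their percentile was 99.98 or above once these lists were shifted by the control's excess over its own. Length-centred, however, 9 of the 17 were higher and 8 lower. What sets the control sedentary libraries apart stays open, and RNA quality was not tested.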

How the results depend on the processing

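Length-centring, the test above 1.5-fold, the scaled standard error, a common q threshold, the use of all listed genes and the reversal set against runners were chosen after seeing the data; the others were planned. Of the other settings' values of the main results, 83 kept their direction and stayed within 1.5 times the reported count, and 37 counts moved further. No gene list passed in opposite directions under different settings, but length-centring turned the split of some whose call was lost or absent, such as ribosomal genes in runners (1 higher and 12 lower, then 7 and 6). Requiring a change of at least 2-fold left 1332 genes higher and 575 lower for cKO over control in sedentary mice, 897 and 325 in runners, 75 and 66 for running in the cKO, and 85 and 54 for running in the control. At 1.5-fold the counts were 2594 and 1937, 1957 and 983, 294 and 249, and 338 and 208. With 1 added to each FPKM and 1.5-fold required they were 1570 and 1449, 992 and 641, 134 and 71, and 162 and 71. These counts fell because the settings remove small changes by construction. The share higher rose with the size required, from 46.5% to 69.8% at 2-fold for sedentary genotype and from 47.1% to 73.4% in runners, and from 54.6% to 61.2% for running in the control, but not for running in the cKO (56.2%, then 53.2%).

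At 1.5-fold in both comparisons, the genotype overlap was 2171 genes in the same and 12 in opposite directions, the reversal 43 and 299, and the running responses 55 and 21. The last of these moved from 50.1% to 72.4% in the same direction; the cause was not tested. Genes whose running response differed numbered 569 with a difference of at least 1.5-fold, 75 by the test above 1.5-fold, and 3035 with the scaled standard error, which stayed within 1.5 times. At 1.5-fold, gene lists past the threshold numbered 5 for cKO over control in runners, 2 for running in the cKO and 3 for running in the control, with fewer called members to test. Smaller losses were from 20 lists to 14 for sedentary genotype at 1.5-fold, from 11 to 8 for running in the control at an FPKM of at least 1, and at q below 0.01 from 21 to 19 in runners and from 20 to 19 in sedentary mice. Length-centred, 5 lists passed for running in the control, against 11 as reported, and 5 differed between the running responses, against 10. Lists also fell from 20 to 17 for sedentary genotype, from 21 to 18 in runners and from 10 to 9 for running in the cKO. The cause of these losses with length-centring was not tested. With a pseudocount of 1, 212 of 591 named gene values moved by over 1 standard error and with 0.1, 10 did; none reversed.

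No paired analysis was possible because the tables hold 1 value per group and what the lane letters mean is not stated. For the same reason leaving out a replicate and a block for the lane letter were not run, and centring on the median of all genes was not run because the tables do not list all genes. Depth is unknown, so no limit of detection can be given.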

Other observations

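The 33 gene lists hold further groups, described here from the same tests; the length-centred values were added after seeing the data. Glucocorticoid responsive genes were higher in the cKO (15 higher and 4 lower in sedentary mice, adjusted exact p = 0.0104; 12 and 2 in runners, adjusted exact p = 0.00961), with 2.57 for Zbtb16 and 1.07 for Fkbp5 in sedentary mice in the authors' deposited table. Ataxia-linked channels and receptors were higher in the sedentary cKO (23 higher, 8 lower, adjusted exact p = 0.00507; 0.0535 length-centred), with 1.61 for Cacna2d2 and 1.58 for Cacna1g in the authors' deposited table, and were evenly split in runners (14 and 13, adjusted exact p = 0.857). Cerebellar patterning transcription factors were higher in the cKO in sedentary mice (15 and 5, adjusted exact p = 0.0244, 0.17 length-centred) and in runners (14 and 3, adjusted exact p = 0.00974). The authors' deposited table gave 3.08 for Lmx1b and 2.91 for Pax8 in sedentary mice, both from low control values (0.122 and 0.107 FPKM). Histone genes were lower in the sedentary cKO (2 and 11, adjusted exact p = 0.0439), with -1.24 for Hist3h2ba and -0.90 for H2afz in the authors' deposited table. ISWI complex genes, Smarca5 among them, numbered 1 higher and 9 lower in cKO runners (adjusted exact p = 0.037, 0.472 length-centred) and 1 higher and 8 lower in the sedentary cKO (adjusted exact p = 0.0679), with -0.44 for Baz2a and -0.42 for Baz1b in runners and 1.20 for Baz1a in sedentary mice in the authors' deposited table. Cholesterol synthesis genes were lower in the sedentary cKO (3 and 14, adjusted exact p = 0.0439, 0.692 length-centred), with -1.03 for Stard4 in the authors' deposited table. Unfolded protein and integrated stress response genes were higher in cKO runners than in control runners (13 and 3, adjusted exact p = 0.016, 0.133 length-centred), with 1.78 for Trib3 and 1.40 for Nupr1 in the authors' deposited table.

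Several lists passed in none of the 4 comparisons. Circadian clock output genes numbered 10 higher and 1 lower with running in the cKO (adjusted exact p = 0.0729), with 0.95 for Per1 and 0.85 for Per2 in the authors' deposited table. Heat shock genes numbered 10 higher and 2 lower there (adjusted exact p = 0.169), and thyroid hormone responsive genes 7 higher and 1 lower (adjusted exact p = 0.169). In sedentary mice, p53 and cell death genes numbered 10 higher and 5 lower in the cKO (adjusted exact p = 0.184), proliferation genes 9 and 8 (adjusted exact p = 0.72), and GABA and glutamate receptor genes 16 and 16 (adjusted exact p = 0.772). Red blood cell genes numbered 3 higher and 2 lower there (adjusted exact p = 0.736), with Alas2 at 4.57 FPKM in cKO sedentary and 1.27 in control sedentary in the authors' deposited table.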
